A study of Mus musculus with 6 samples.

How the data were processed

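Ribosome footprints of 24 to 36 nt were sequenced from 6 libraries of mouse Lin-c-Kit+ cells, 3 from WT and 3 from Mov10 knockout mice, after RNase I digestion of cycloheximide-treated cells, a sucrose cushion and PCR amplification. The labels do not say whether the replicates are separate animals, so p-values may measure technical spread only. The aligner, the counting tool and the annotation are not given in the sources used here, nor whether counting used the strand, and the genome build in the submitters' processing notes is GRCm39.

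The signal values deposited by the authors are read counts per gene divided by 1 size factor per library, as shown by the values, which are whole multiples of 1 step per library (within 0.05 of a read) in all genes with reads but 5. The deposited log2 fold changes, knockout over WT, were made by the authors with a tool that is not stated, and are drawn toward 0 for genes with few reads. The deposited p-values and adjusted p-values are the authors' own, from a test that is not stated, and DESeq2 with a fold-change prior gave nearly the same p (median difference in log10 p of 3.83e-05 over 28098 genes). The table listed 56748 genes, of which 28136 had reads, and 2693 had no symbol.

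Reads were recovered by dividing each value by the step of its library, which gave 2260348 to 2499634 reads per WT library and 1118345 to 1352517 per knockout library. The reads carry no molecular identifiers, so floors of 3 reads cover counting error only. Genes with a mean of at least 1 normalized read were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1) with genotype as the only term and a variance trend, and called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 over 31 lists, and with the correlation estimated. For each list 10000 random lists were drawn from the 50 genes on either side of each member in mean abundance, with seed 1. Composition was compared with exact two-sided permutation tests over 20 regroupings, with a smallest possible p of 0.1. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

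The groups, gene lists, tests, first alternatives and the rule for named genes were chosen before the data were examined. The plan named edgeR for counts and limma for normalized values, and the deposited unit led to limma, with a variance trend that the plan did not name. The rule named Mov10 and Camp, the 10 higher and 10 lower protein-coding genes with the smallest p among those past the threshold whose groups do not overlap, and up to 4 members per list with the smallest p, plus members needed to show the opposite direction. A few genes that the rule names are not reported. Camp, Rps29, Igkc, Ssr4 and Rpl27 were left out of the genome-wide fit and the lists after their values were seen, because they are not whole multiples of their own library's step, and Camp was fitted with them included.

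The first alternatives were a replicate block, DESeq2 1.42.0 size factors and its Wald test, upper-quartile scaling, library totals, limma-voom, robust empirical Bayes, no filter, a mean of at least 50 reads, protein-coding genes, no 20 most abundant genes, an adjusted p under 0.01, a fold of at least 2, a pseudocount of 0.1, an estimated correlation and fry for the lists, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on recovered reads, TMM scaling, cyclic loess, no variance trend, thinning of all libraries to equal depth, and both readings of the 5 genes.

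The procedure was checked on simulated data for the comparison of knockout and WT. With 17206 genes, limma recovered 52% of 100 genes changed 2-fold and 81% of 100 changed 4-fold, and called 6 of 16981 unchanged genes. With 10719 genes, edgeR recovered 57% of 100 genes changed 2-fold and 82.8% of 99 changed 4-fold. The simulation gave both genotypes the same spread per gene and no trend of fold change with abundance. The data differ in both respects, so these rates need not hold for them.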

Results

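Ribosome profiling sequences the short stretches of mRNA that translating ribosomes shield from a nuclease, so that the reads on a gene count its ribosome footprints. Footprints were read in Lin-c-Kit+ mouse cells, a gate that the labels call hematopoietic stem cells, taken 12 days after irradiation with 4.5 Gy. The 6 libraries formed 2 groups, 3 from wild-type (WT) mice and 3 from Mov10 knockout mice. The WT libraries held 2407091, 2499634 and 2260348 reads and the knockout libraries 1352517, 1118345 and 1257956, so that depth and genotype went together. A gene with no read in a library had a floor of 3 reads, which is 1.84 to 2.04 normalized reads in the WT libraries and 4.02 to 4.85 in the knockout libraries. Footprint levels reflect both the amount of an mRNA and how often it is translated, and mRNA levels were not analysed here, so the changes are not changes in translation per mRNA.

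All levels are normalized reads, given as mean ± SD with n = 3 libraries per genotype, and folds are knockout over WT ("higher") or WT over knockout ("lower"). The WT libraries resembled each other more than the knockout libraries did, with Spearman correlations across genes of 0.978 to 0.979 within WT and 0.867 to 0.869 within the knockout. Correlations between the genotypes were 0.858 to 0.866, almost as high as within the knockout. The first principal component held 69.6% of the variance of 6706 genes and separated the genotypes. Genes are not independent replicates, and no test was made on these correlations.

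Mov10, the gene that the labels name as knocked out, encodes an RNA helicase known from RNA silencing and decay, and its footprints show how far the libraries follow their labels. Mov10 (chromosome 3, 104702152 to 104725879, GRCm39) had 107 ± 3.13 normalized reads in WT and 62.1 ± 23.4 in the knockout, and was lower in 3 of 3 knockout libraries than in any WT library. Its log2 fold change was -0.84 (SE 0.27) and did not pass the threshold (adjusted p = 0.0598). Knockout replicate 2 held 89.0 normalized reads of Mov10 against 51.0 and 46.3 in the other knockout libraries. Without that library Mov10 was lower by more and passed, with a log2 fold change of -1.12 (adjusted p = 0.00692, within 0.00692 to 0.205 when each library was left out in turn). The values are totals over the whole gene, so they do not show which part of Mov10 the remaining reads lie on.

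Camp encodes the cathelicidin antimicrobial peptide of neutrophil granules, and the series title names it as a target of Mov10. In Camp (chromosome 9, 109676447 to 109678685, GRCm39) the 2 possible readings of the table give opposite directions. With the columns as headed, Camp was lower in 3 of 3 knockout libraries, at 4465 ± 423 normalized reads in WT and 1898 ± 229 in the knockout, a ratio of 0.425 and a log2 fold change of -1.24 (SE 0.10, adjusted p = 8.54e-05). With the genotypes of this row exchanged, Camp was higher in 3 of 3 knockout libraries, by 2.35-fold, with a log2 fold change of 1.24 and the same adjusted p. The exchange is considered because the values of Camp and of Rps29, Igkc, Ssr4 and Rpl27 were, within 0.01 of a read, whole multiples of the value of 1 read in the same-numbered library of the other genotype, in 30 of 30 values. In all other genes with reads, values above 0 were whole multiples of the value of 1 read in their own library, within 0.05 of a read. The table does not state which reading holds, so both are given for these 5 genes, though the multiples of the other genotype's reads argue against the columns as headed.

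The other genes of this kind were Rps29 and Rpl27, both ribosomal protein genes, Igkc, the constant part of the immunoglobulin kappa chain, and Ssr4, a subunit of the translocon-associated complex of the endoplasmic reticulum. As headed, all of them were higher in the knockout, Rps29 by 16.1-fold, Ssr4 by 4.90-fold, Igkc by 4.16-fold and Rpl27 by 1.99-fold. With the genotypes exchanged, each was lower by the same factor. These 5 genes were left out of the genome-wide counts and of the lists.

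**Figure D1:**
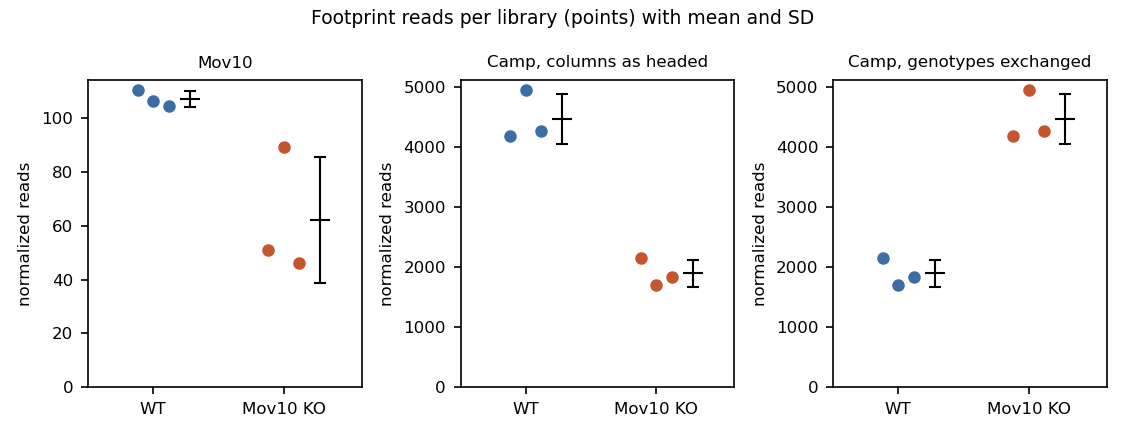
Normalized footprint reads of Mov10 and Camp in each library (points), with the mean and SD of the 3 libraries of each genotype beside them. Mov10 is lower in all 3 knockout libraries, and Camp is shown with the columns as headed (WT 4465, knockout 1898) and with the genotypes exchanged.

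Across the genome, limma tested 17114 genes and called 3628 of them changed between the genotypes, 1757 higher and 1871 lower in the knockout, and 2408 of them by 2-fold or more. Of the 13457 protein-coding genes tested, 1522 were higher and 1420 lower. In 6818 of the tested genes (39.8%) all knockout libraries lay on one side of all WT libraries, where chance gives 10%. An edgeR test of the recovered reads called 3213 of 10891 genes, 1801 higher and 1412 lower, and 2807 genes were called by both tools, each in the same direction. The number of calls fell to 1449, 1284 and 1239 when WT replicates 1, 2 and 3 were left out in turn, and more among the lower genes, of which 501, 406 and 403 were called, against 948, 878 and 836 higher genes. The higher genes then made up 65.4%, 68.4% and 67.5% of the calls. Without knockout replicates 1, 2 and 3 in turn, 4585, 4447 and 4494 genes were called. The fit took 1 spread per gene for both genotypes, while the knockout libraries scattered more than the WT libraries. How far this accounts for calls lost without a WT library was not tested. The balance of directions also depended on the scaling, as the higher genes made up 48.4% of the calls with the authors' scaling, 62.7% with upper-quartile scaling and 30.8% with library totals.

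The 10 protein-coding genes higher in the knockout with the smallest p spanned several cell functions. Lratd1, which encodes an LRAT domain protein, had no read in any WT library and 4012 ± 435 normalized reads in the knockout, at least 2064-fold higher against the floor of 3 reads per library (adjusted p = 6.56e-08, chromosome 12, 14196831 to 14202055). Ppig, a nuclear cyclophilin, rose from 440.1 ± 29.3 to 8221 ± 795, 18.7-fold higher. Map1s, a microtubule-associated protein, rose 17.9-fold to 3057 ± 466, Ccdc125 rose 13.5-fold, and Banf1, a chromatin-binding factor of the nuclear envelope, rose 10.3-fold. Phc3, a Polycomb subunit, rose 8.20-fold, Prg3, an eosinophil granule protein, 4.72-fold, and Pcm1, a protein of centriolar satellites, 3.62-fold. Psap, the precursor of the lysosomal saposins, rose from 4779 ± 261 to 11171 ± 333, 2.34-fold higher. The adjusted p of the 10 genes lay between 6.56e-08 and 4.45e-06. Each was higher in 3 of 3 knockout libraries, as the rule for naming them required.

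The 10 protein-coding genes lower in the knockout with the smallest p included mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, which fell from 3911 ± 102 to 1176 ± 16.7, 3.32-fold lower (adjusted p = 8.10e-07). S100a8, a calcium-binding protein abundant in neutrophils, fell from 2246 ± 101 to 371 ± 57.4, 6.06-fold lower. Gpr52, an orphan receptor gene, fell 21.6-fold, from 1364 ± 289 to 63.0 ± 26.5. Bcas2, a spliceosome component, fell from 217 ± 12.4 to 19.8 ± 3.79. Snapc3, a factor for snRNA transcription, fell 7.04-fold, H1f3, a linker histone, 5.91-fold, and Actg1, a cytoplasmic actin, 5.76-fold. Laptm4a, a lysosomal membrane protein, fell 4.44-fold, Ankrd28 2.65-fold and Ivns1abp 2.53-fold. The adjusted p of these 10 genes lay between 8.10e-07 and 3.88e-05. Each was lower in 3 of 3 knockout libraries, as the rule for naming them required. Among the 20 genes, Ppig, Banf1, Ankrd28, Snapc3, Gpr52 and Ivns1abp overlap another gene with reads, Gpr52 for example Rabgap1l, and Actg1 and mt-Co1 have close copies elsewhere in the genome, so their reads cannot be assigned with certainty.

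**Figure D2:**
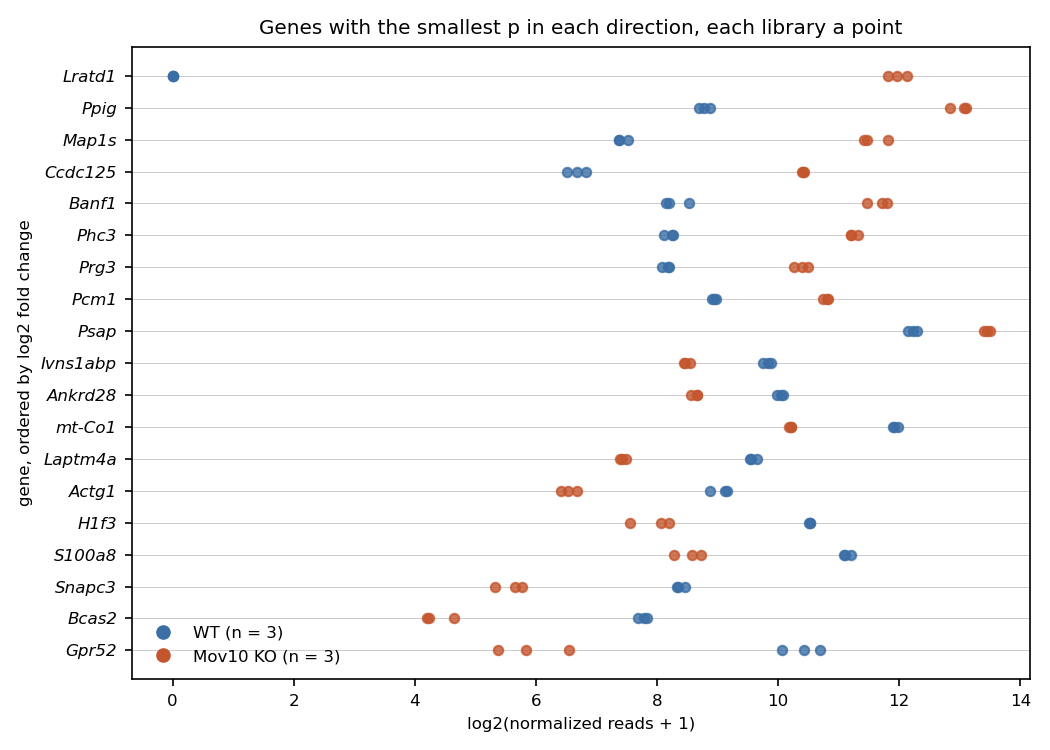
Footprint level of protein-coding genes with the smallest p in each direction, as log2 of normalized reads plus 1, with each library a point. The 3 knockout libraries lie on one side of the 3 WT libraries for every gene shown, as the rule for naming genes required. Lratd1 lies at 0 in WT.

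Of 31 gene lists fixed in advance, 8 passed camera at an adjusted p under 0.05, with B cell, heat shock, erythroid and translation factor genes higher and stem cell, histone, ribosomal protein and interferon-stimulated genes lower. With the correlation between members estimated from the data, no list passed (adjusted p from 0.256 upwards). In the erythroid, histone, ribosomal protein and translation factor lists the estimated correlation was -0.021, -0.0064, -0.0021 and 0.00091, below the preset 0.01. Correlation between members therefore does not account for the lost calls of these lists. In the B cell, heat shock, interferon-stimulated and stem cell lists it was 0.044, 0.127, 0.036 and 0.012. The stem cell value was near the preset, yet the unadjusted camera p of that list went from 0.00448 to 0.0496. Correlation need not account for its lost call either, and what ended the calls was not tested. The median log2 fold change of all tested genes was -0.17 with the authors' scaling, which upper-quartile scaling moved by 0.18 and library totals by -0.22. List medians are therefore given with their distance from that of all genes. In the same libraries, genes read often tended to be higher in the knockout, so each list was also set against 10000 random lists of similar abundance. The other 23 lists did not pass, with adjusted p between 0.0864 and 0.972. Members beyond the 4 with the smallest p in a list are named where they make up a count of 5 or fewer, and these were chosen after their values were seen.

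B cell genes were higher in the knockout, 8 of 18 tested members against 1 lower, and the same numbers when adjusted over the list alone. Rag1, a recombinase of lymphocyte precursors, rose from 28.4 ± 3.44 to 168 ± 51.8, 5.92-fold higher, and Cd22, a B cell surface receptor, 4.69-fold. Jchain, which joins immunoglobulin chains, rose 3.16-fold and Ighm, the mu heavy chain, rose from 764 ± 14.1 to 1373 ± 17.4, 1.80-fold higher. Dntt, a polymerase of early lymphoid cells, fell 1.82-fold. The share of reads in immunoglobulin constant genes was 0.175% ± 0.0130 in WT and 0.308% ± 0.0199 in the knockout, with Igkc left out, and in variable genes 0.0276% ± 0.00209 in WT and 0.0937% ± 0.00674 in the knockout (exact two-sided permutation p = 0.1 for both, the smallest that 3 against 3 allows). Igkc itself was 4.16-fold higher in the knockout as headed and 4.16-fold lower with the genotypes exchanged. The list median was 1.15, 1.33 above that of all genes and higher than that of all 10000 matched lists (adjusted p = 0.000953, and adjusted p = 0.256 with an estimated correlation, in a range of 2.36e-05 to 0.256 over 19 alternatives). The call of Dntt was lost without each WT library in turn, with an adjusted p of up to 0.147.

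Erythroid genes were more often higher than lower in the knockout, 15 of 29 tested members against 4 lower, and 16 against 6 when adjusted over the list alone, while with library totals 9 were higher and 6 lower. Without WT replicates 1, 2 and 3 in turn, 10, 10 and 9 were higher and 2, 1 and 1 lower. Slc4a1, the band 3 anion exchanger, rose from 314 ± 26.2 to 904 ± 105, 2.88-fold higher. Cpox, an enzyme of heme synthesis, rose 2.36-fold and Ank1, an ankyrin of the red cell membrane, 1.75-fold. Lower were Hba-a1, an alpha globin gene with a near-identical copy, at 23.0 ± 4.42 in WT and 0.539 ± 0.934 in the knockout, and Aqp1, Blvrb and Slc25a37. The list median was 0.45, 0.63 above that of all genes and above 98.7% of matched lists (adjusted p = 0.0347, and adjusted p = 0.256 with an estimated correlation). The adjusted p was 0.0573 without knockout replicate 2, 0.0508 with a mean of at least 50 reads and 0.268 after cyclic loess. Over 19 alternatives it ranged from 0.000751 (fry, which tests against no change and not against other genes) to 0.268. The calls of Aqp1, Blvrb and Slc25a37 were lost without some WT libraries, with adjusted p of up to 0.0779, 0.0916 and 0.106.

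Heat shock and proteostasis genes were higher in the knockout, 13 of 25 tested members against 0 lower, and 15 against 1 when adjusted over the list alone. Hsp90ab1, a cytosolic chaperone, rose from 1702 ± 39.4 to 3379 ± 147, 1.99-fold higher. Cct7, a subunit of the TRiC chaperonin, rose 2.62-fold, Psmd1, a subunit of the 26S proteasome, 2.75-fold and Hspd1, the mitochondrial chaperonin, 1.75-fold. Hspa8, the member lower when adjusted over the list alone, had 2035 ± 160.3 normalized reads in WT and 1714 ± 156 in the knockout and did not pass over all genes (adjusted p = 0.0767). The median of heat shock and proteostasis genes was 0.46, 0.63 above that of all genes and above 92.2% of matched lists (adjusted p = 0.00220, and adjusted p = 0.324 with an estimated correlation). After cyclic loess, which removes the trend with abundance, the adjusted p was 0.217, in a range of 5.73e-05 to 0.324 over 19 alternatives.

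Ribosomal protein genes were more often lower than higher in the knockout. Of 75 tested ribosomal protein genes 27 were lower and 10 higher, 29 and 12 when adjusted over the list alone, and 38 were not called. With upper-quartile scaling 12 were higher and 21 lower, and 8, 6 and 7 were higher and 14, 13 and 12 lower without WT replicates 1, 2 and 3 in turn. Rplp0 of the ribosomal stalk fell from 529 ± 19.6 to 179.6 ± 24.9, 2.95-fold lower, Rpl30 fell 3.66-fold and Rpl31 2.77-fold. The share of reads in ribosomal protein genes was 1.07% ± 0.0134 in WT and 0.795% ± 0.00820 in the knockout (exact two-sided permutation p = 0.1). The median of ribosomal protein genes was -0.57, -0.40 relative to all genes, below all 10000 matched lists (adjusted p = 0.0413, and adjusted p = 0.256 with an estimated correlation). The adjusted p was 0.0969 and 0.0649 without knockout replicates 2 and 3, 0.0861 with a pseudocount of 0.1, 0.0617 with upper-quartile scaling and 0.0895 with Rps29 and Rpl27 as headed. Over 19 alternatives it ranged from 0.000980 (fry, a test against no change) to 0.256. These genes have many processed pseudogenes, with which they can share reads, and the share of reads in all processed pseudogenes was 0.448% ± 0.00832 in WT and 0.633% ± 0.00531 in the knockout (exact two-sided permutation p = 0.1), a difference in the other direction.

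Of 35 tested translation factor genes 11 were higher and 2 lower, and the same numbers when adjusted over the list alone (adjusted p = 0.0413, and adjusted p = 0.256 with an estimated correlation). With library totals 7 were higher and 5 lower, after cyclic loess 6 were higher and 5 lower, and without WT replicates 1, 2 and 3 in turn 7, 7 and 7 were higher and 2, 2 and 2 lower. Eif4g1, the scaffold of the cap-binding complex, rose from 919 ± 73.5 to 2551 ± 66.9, 2.77-fold higher, Eif3e rose 3.13-fold and Eef1a1, the elongation factor that delivers tRNA, 1.83-fold. Eif4a2, an RNA helicase of initiation, fell 2.43-fold and Eif4e, the cap-binding protein, 2.46-fold. The median of translation factor genes was 0.12 and turned to -0.11 with library totals, which lowered the median of all genes as well, and it was 0.29 above that of all genes but above only 22.5% of lists matched in abundance. The adjusted p was 0.0549, 0.0908 and 0.0763 without WT replicates 1, 2 and 3, 0.109 without knockout replicate 2, 0.0972 with TMM scaling, 0.212 with library totals, 0.0655 with a replicate block, 0.282 with a mean of at least 50 reads and 0.997 after cyclic loess. Over 19 alternatives it ranged from 0.00409 (fry, a test against no change) to 0.997.

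Histone genes were lower in the knockout, with 9 of 35 tested replication-dependent histone genes lower and 3 higher, 11 and 3 when adjusted over the list alone. The linker histone H1f3 fell from 1467 ± 12.5 to 248 ± 55.1 and H1f1 fell 1.76-fold. H2ac6 rose 2.10-fold, the linker histone H1f5 1.81-fold and H3c7 2.51-fold. Copies of core histone genes are nearly identical, so reads cannot be assigned to single members with certainty. The median of replication-dependent histone genes was -1.39, -1.22 relative to all genes, below all 10000 matched lists (adjusted p = 0.0401, and adjusted p = 0.256 with an estimated correlation). The adjusted p was 0.0573 without knockout replicate 2, 0.0861 with a pseudocount of 0.1 and 0.353 with a mean of at least 50 reads. Over 19 alternatives it ranged from 0.000871 (fry, a test against no change) to 0.353. The call of H3c7 was lost without any 1 of the WT libraries or knockout replicates 2 and 3 (adjusted p up to 0.118). The lower members called without WT replicates 1, 2 and 3 in turn numbered 6, 4 and 6, and the 4 were H1f1, H1f3, H2bc12 and H3c2.

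Interferon-stimulated genes were lower in the knockout as a list, with 10 of 42 tested members lower against 3 higher, and 14 against 5 when adjusted over the list alone, but the balance of its called members did not hold in every setting. With upper-quartile scaling 5 were higher and 6 lower, and without WT replicates 1, 2 and 3 in turn 3, 3 and 3 were higher and 2, 3 and 2 lower. The lower members then called were Zbp1 and Ifi203, with Oas2 where WT replicate 2 was left out, and the 3 higher members kept their calls without each of the 6 libraries. Zbp1, a sensor of unusual nucleic acids, fell from 31.7 ± 9.86 to 0.539 ± 0.934, and Ifi203 fell 5.60-fold. Gbp3, a guanylate-binding protein, rose 3.90-fold, Ifi204 rose 6.11-fold and Gbp7 2.07-fold. The median of interferon-stimulated genes was -0.78, -0.61 relative to all genes, below all 10000 matched lists, and it was -0.58 with the member at 0 in 1 genotype placed at its bound (adjusted p = 0.0413, and adjusted p = 0.324 with an estimated correlation). The adjusted p was 0.0954 without WT replicate 3, 0.0781, 0.0573 and 0.0563 without knockout replicates 1, 2 and 3, 0.132 with edgeR, 0.0739 with upper-quartile scaling, 0.0861 with a pseudocount of 0.1 and 0.353 with a mean of at least 50 reads. Over 19 alternatives it ranged from 0.0112 (fry, a test against no change) to 0.353.

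Hematopoietic stem and multipotent progenitor genes were lower in the knockout, 6 of 26 tested members against 1 higher, and 7 against 1 when adjusted over the list alone. Txnip, a regulator of thioredoxin and glucose uptake, fell from 553 ± 21.2 to 364 ± 20.2, 1.52-fold lower. Esam, an adhesion molecule of stem cells and endothelium, had 7.30 ± 1.13 normalized reads in WT and 0 in the knockout, at least 1.66-fold lower against a floor of 3 reads per library. Hoxb4 had 4.97 ± 1.89 in WT and 0 in the knockout, at least 1.13-fold lower against that floor. Both bounds cover counting error only and may not hold. The knockout libraries scattered more than counting gives, with squared deviations 5.09 to 5.19 times those of counting for genes of 10 to 50 reads at equal depth. Angpt1, a ligand of the Tek receptor, rose 1.71-fold. The median of hematopoietic stem and multipotent progenitor genes was -0.53, -0.36 relative to all genes and above 6.37% of matched lists, and -0.37 with members at 0 in 1 genotype at their bounds (adjusted p = 0.0347, and adjusted p = 0.256 with an estimated correlation). The adjusted p was 0.0505 and 0.118 without knockout replicates 1 and 3, 0.175 with edgeR and 0.282 with a mean of at least 50 reads. Over 19 alternatives it ranged from 0.000980 (fry, a test against no change) to 0.282. Without any 1 of the WT libraries only Esam and Txnip were called lower, and the calls of Hoxb4, Ifitm1, Msi2 and Hmga2 were lost (adjusted p up to 0.0610, 0.146, 0.119 and 0.0777). Angpt1 was lost without WT replicates 1 and 2 (adjusted p up to 0.0584), while 10 members were lower and 1 higher without knockout replicate 2.

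**Figure D3:**
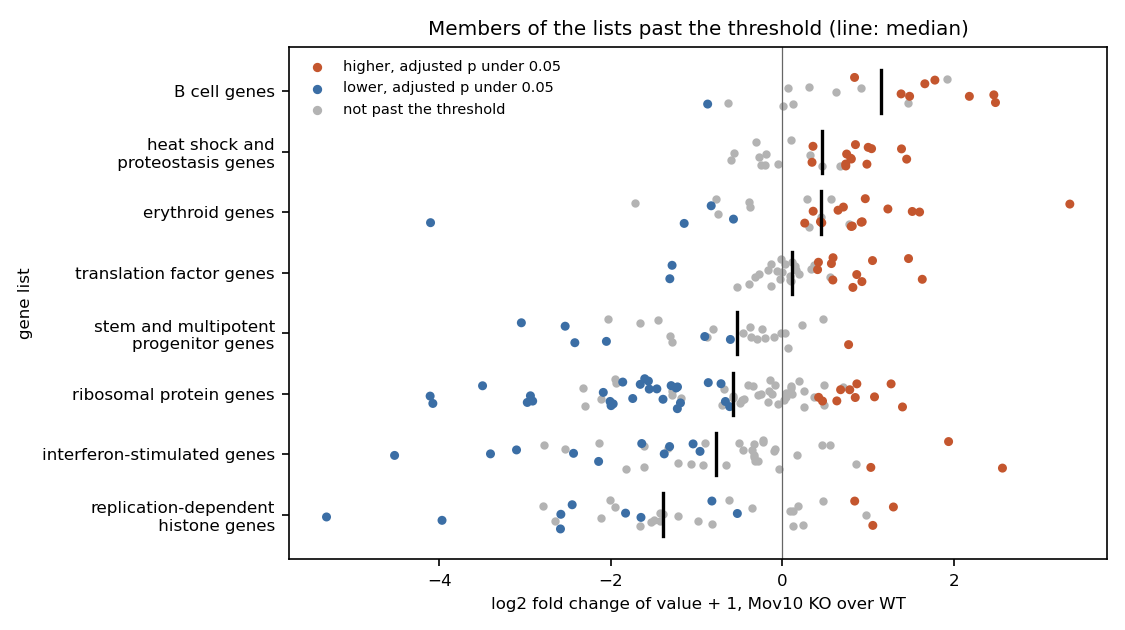
Log2 fold change of normalized reads plus 1, knockout over WT, for the tested members (points) of the 8 lists past the threshold, with the list median as a line. Colored points are members called higher or lower, and medians run from -1.39 for replication-dependent histone genes to 1.15 for B cell genes.

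Neutrophil granule genes, the class to which Camp belongs, had called members in both directions with the authors' scaling, and more of them were lower after cyclic loess. Of 15 tested primary granule genes 5 were higher and 4 lower, and 5 and 5, with Cst7, when adjusted over the list alone (adjusted p = 0.935 for the list). Mpo, the myeloperoxidase, rose from 12660.3 ± 1426 to 29006 ± 782, 2.29-fold higher, and Calr, a chaperone, rose 2.32-fold, with Ctsg, Cebpe and Prss57 also higher. Prtn3, the serine protease proteinase 3, fell from 1745 ± 174 to 878 ± 24.5, with Serpinb1a, Srgn and Nkg7 also lower. Of 21 tested secondary and tertiary granule genes, Camp left out, 6 were higher and 5 lower, and 6 and 6 when adjusted over the list alone (adjusted p = 0.972). The gelatinase Mmp9 rose 2.08-fold, while Mmp25 fell 4.75-fold, Chil3, a chitinase-like protein, 2.72-fold, Cd177, a neutrophil surface protein, 2.00-fold, Ngp, a granule protein, 1.67-fold and Mmp8, the neutrophil collagenase, 3.58-fold. For primary granule genes the median (-0.16), above 2.02% of matched lists with the authors' scaling, and the mean were below 0 while camera, which compares with all other genes, pointed up. After cyclic loess 2 were higher and 7 lower among primary and 3 were higher and 8 lower among secondary and tertiary granule genes. Leaving out WT replicates 1, 2 and 3 in turn, 3, 3 and 3 were higher and 2, 2 and 2 lower among the former and 4, 3 and 3 were higher and 4, 4 and 4 lower among the latter. Antimicrobial peptides and proteins, Camp left out, had 6 of 18 tested members higher and 4, S100a8, Prtn3, Ngp and Ear1, lower, the same numbers when adjusted over the list alone (adjusted p = 0.948), and 1 was higher and 10 lower after cyclic loess, when the list passed as lower (adjusted p = 0.0107, in a range of 0.0107 to 0.984 over 19 alternatives). With the authors' scaling its median (-0.058), above 0.840% of matched lists, and its mean were below 0 while camera pointed up. The calls of Cebpe, Prss57, Srgn, Nkg7, Mmp8 and Ear1 were lost in leave-outs of 1 library, Cebpe without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.0920), Prss57 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.131), Srgn without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.0761), Nkg7 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.0869), Mmp8 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.102), Ear1 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.101). The call of Mpo was lost after cyclic loess, with a log2 fold change of 0.11 in place of 1.20, and Ctsg, 1.46-fold higher with the authors' scaling, turned to -0.0050.

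The share of reads in mitochondrially encoded protein genes was 0.454% ± 0.0112 in WT and 0.212% ± 0.0176 in the knockout (exact two-sided permutation p = 0.1). Of 9 tested members 4 were lower, mt-Co1, mt-Nd3, mt-Cytb and mt-Nd2, and 1 was higher, mt-Nd5, and 5, with mt-Atp8, and 1 when adjusted over the list alone. mt-Cytb fell 2.74-fold, mt-Nd5 rose 1.80-fold, and mt-Co2, mt-Co3 and mt-Nd4l were listed at 0 in every library. The median of mitochondrially encoded protein genes was -1.22, and the list did not pass (adjusted p = 0.125, in a range of 0.000715 to 0.353 over 19 alternatives). It passed as lower after cyclic loess (adjusted p = 0.0200) and with edgeR (adjusted p = 0.00365). The low end of the range came from fry, which tests against no change and not against other genes, and with which the list passed as lower (adjusted p = 0.000715). The call of mt-Nd2 was lost without each WT library in turn (adjusted p up to 0.0897).

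Genes of the RNA silencing and decay machinery in which Mov10 works had 5 of 38 tested members higher and 9 lower with the authors' scaling, and 6 and 14 when adjusted over the list alone. The balance depended on the scaling, as 7 were higher and 3 lower with upper-quartile scaling and 3 were higher and 16 lower with library totals. It also rested on the WT libraries, as 3, 4 and 3 were higher and 3, 0 and 0 lower without WT replicates 1, 2 and 3 in turn, the 3 lower members being Cnot6, Dcp1a and Smg1. Over all genes, lower calls fell in the same settings from 1871 to 501, 406 and 403, so a loss of lower calls is not particular to this list. Smg6, an endonuclease of nonsense-mediated decay, rose 3.83-fold, Zc3hav1, an antiviral RNA-binding protein, 2.42-fold and Dicer1, the nuclease that makes microRNAs, 1.89-fold, with Fxr1 and Xrn1 also higher, while Dcp1a, a decapping factor, fell 4.89-fold. The list did not pass (adjusted p = 0.553), but passed as lower after cyclic loess (adjusted p = 0.0480, in a range of 0.0480 to 0.748 over 19 alternatives), and its median of -0.26 lay above 0.520% of matched lists. All 9 lower calls were lost without WT replicate 2 and without WT replicate 3, with a highest adjusted p per gene of 0.0565 to 0.188, and among the higher members calls were lost for Fxr1 without WT replicate 1 or WT replicate 3 (adjusted p up to 0.0695), Xrn1 without WT replicate 1 or WT replicate 2 or WT replicate 3 or knockout replicate 2 (adjusted p up to 0.125).

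Small RNA genes also differed in their share of reads. Reads in snoRNA genes made up 0.535% ± 0.0412 in WT and 0.179% ± 0.0130 in the knockout. Of 35 tested snoRNA genes 9 were called higher and 8 lower, so the lower share was not a fall across these genes as a class. Reads in miRNA genes made up 0.0368% ± 0.00465 in WT and 0.250% ± 0.0542 in the knockout. Mir1981, singled out after its values were seen, held 330 reads in WT and 5481 in the knockout, and without it the share in miRNA genes was 0.0322% ± 0.00386 in WT and 0.103% ± 0.0224 in the knockout. Protein-coding genes held 95.9% ± 0.132 in WT and 95.5% ± 0.0482 in the knockout. The 10 most read genes took 4.92% ± 0.221 in WT and 6.81% ± 0.0621 in the knockout. All 16 measures of composition differed with an exact two-sided permutation p = 0.1 and a Benjamini-Hochberg adjusted p = 0.1, the smallest that 3 libraries against 3 allow, so none could pass.

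The authors' table called 3305 genes at its adjusted p under 0.05, the 5 genes with 2 readings left out, 1845 higher and 1460 lower in the knockout. Of these, 2906 were also called by limma, all in the same direction. Its value for Mov10 was a log2 fold change of -0.75 with an adjusted p of 0.058. For Camp the fold-change cell held -0.37, which equals the log10, not the log2, of the ratio of the means as headed, beside an adjusted p of 1.92e-38. The same held for Rps29, Igkc, Ssr4 and Rpl27 and for no other row.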

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

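Tests with edgeR, TMM scaling, cyclic loess, no variance trend, equal depth and both readings of the 5 genes were chosen after the data were seen. The 20 genes named by smallest p kept their direction and call under every alternative that tested them and without each library (18 of them where the 20 most abundant genes, which hold the other 2, were dropped). The 3628 changed genes became 1427 at an adjusted p under 0.01 and 2408 at a fold of at least 2, both by construction, and 1239 to 4585 with 1 library left out. The log2 fold change of Mov10 footprints passed with library totals (-1.06), TMM scaling (-0.93), limma-voom (-0.84) and a mean count of at least 50 (-0.84). It was smaller and did not pass with upper-quartile scaling (-0.64, adjusted p = 0.153), equal depth (-0.71, adjusted p = 0.124) and cyclic loess (-0.73, adjusted p = 0.101). Without a variance trend in limma it did not pass either (adjusted p = 0.126). With 1 library left out it was -1.12 to -0.66, and the cause was not tested. The number of gene lists called was 8, and it was 12 with no filter, 3 with a mean count of at least 50, 5 with a pseudocount of 0.1, 0 with an estimated correlation, 17 with fry, which asks another question, and 3 to 7 with 1 library left out, not always the same lists. Camp footprints had a log2 fold change of -1.24 as headed and 1.24 with the 5 rows exchanged. As headed it was -1.04 with upper-quartile scaling, -1.47 with library totals and -1.90 after cyclic loess. The exchanged reading was not fitted with these scalings. Under cyclic loess the direction turned for Ctsg footprints (-0.0050), Prg2 footprints (-0.41) and, among other called list members, for S100a9, Tfrc, Mki67, Mcm3, Mcm6, Eif3b, Hspa4 and Hsp90aa1, all higher with the authors' scaling, and the list of antimicrobial peptides and proteins (adjusted p = 0.0107, in a range of 0.0107 to 0.984 over 19 alternatives), and the cause was not tested. The mean Spearman correlation between the genotypes, 0.861, was 0.800 with no filter, 0.752 with a mean count of at least 50 and 0.893 for protein-coding genes. Of the comparisons of single lists with an alternative, 531 kept direction and call, 18 came to pass, 38 no longer passed and 1 reversed, and of those of single named genes 3678, 30, 215 and 2. With a replicate block 3245 genes were called, and the deviations of same-numbered libraries correlated across genes by -0.02, -0.0052 and -0.01, so the numbers do not pair the samples. Depth limits genes near 3 reads per library.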

Other observations

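Tests chosen only after the result was seen were both tests of the 5 irregular genes, the tests of depth and of variation with level for the scatter of the knockout libraries, cyclic loess, and the choice of genes found in 1 genotype. Several lists did not pass while single members changed. Of 29 tested ATF4 and unfolded protein response genes 7 were higher and 2 lower, and 10 and 3 when adjusted over the list alone (adjusted p = 0.0864), with Hspa5, the main chaperone of the endoplasmic reticulum, 2.16-fold higher at 7626 ± 204 normalized reads in the knockout and Canx, calnexin, 2.05-fold higher. Of 36 cell cycle genes 14 were higher and 6 lower, and 15 and 7 when adjusted over the list alone (adjusted p = 0.121), with Rrm1, a ribonucleotide reductase subunit, 2.02-fold higher and Cdk6, a kinase of the G1 phase, 2.05-fold lower. Of 30 DNA repair genes 7 were higher and 0 lower, and 10 and 3 when adjusted over the list alone (adjusted p = 0.173), with the mismatch repair gene Msh6 4.01-fold and Brca1 2.66-fold higher. Lower among the ATF4 and unfolded protein response genes were Dnajb9 and Slc7a5. Without WT replicates 1, 2 and 3 in turn, 7, 6 and 6 were higher and 0, 0 and 0 lower for ATF4 and unfolded protein response genes, 10, 10 and 9 were higher and 3, 4 and 3 lower for cell cycle genes and 4, 4 and 3 were higher and 0, 0 and 0 lower for DNA repair genes. Without knockout replicates 1, 2 and 3 in turn, 1, 3 and 2 DNA repair genes were lower, Fanca, then H2ax, Nbn and Xrcc2, then Mre11a and Xrcc6, chosen after their values were seen. These balances also depended on the scaling, as with library totals 5 were higher and 5 lower for DNA repair genes and 10 were higher and 9 lower for cell cycle genes, and the medians of these lists and of ATF4 and unfolded protein response genes turned below 0. With upper-quartile scaling 12 were higher and 0 lower for DNA repair genes, 16 were higher and 4 lower for cell cycle genes, which then passed (adjusted p = 0.0406, with a range of 0.00654 to 0.824 over 19 alternatives), and 11 were higher and 1 lower for ATF4 and unfolded protein response genes, which also passed (adjusted p = 0.0439, and 0.0103 with edgeR, with a range of 0.00130 to 0.795 over 19 alternatives). The low ends of both ranges came from fry, which tests against no change and not against other genes.

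Of 27 tested inflammatory and NF-kB genes 6 were higher and 2 lower, and 7 and 2 when adjusted over the list alone (adjusted p = 0.216). The transcription factors Junb, Jun and Fos were 4.67-fold, 3.21-fold and 2.58-fold higher, and Tnfaip2 and Ccl9 were lower. The median of this list was -0.12, while its mean was 0.11 and camera pointed up, and the median turned above 0 with upper-quartile scaling. Of 15 dendritic cell genes 5 were higher, the MHC class II gene H2-Aa 4.66-fold, its invariant chain Cd74 2.97-fold, and Tcf4, Irf4 and H2-Ab1, and 0 lower, and the same numbers when adjusted over the list alone (adjusted p = 0.376), while median and mean were below 0 and camera pointed up, and the median turned above 0 with upper-quartile scaling. Of 12 stromal and endothelial genes Col1a1, Col1a2 and Col3a1 were higher, Col1a1 2.27-fold, and Pecam1 lower, and the same numbers when adjusted over the list alone (adjusted p = 0.164). Flt3 and Siglech came to be lower without knockout replicate 1, and Ccr9 without knockout replicate 3. Members named to complete counts of 5 or fewer were chosen after their values were seen, and calls lost in leave-outs of 1 library were Ccl9 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.104), Tcf4 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.0989), Irf4 without WT replicate 1 or WT replicate 2 or WT replicate 3 or knockout replicate 1 or knockout replicate 2 (adjusted p up to 0.112), H2-Ab1 without WT replicate 1 or WT replicate 2 or WT replicate 3 or knockout replicate 3 (adjusted p up to 0.168), Col3a1 without WT replicate 1 or WT replicate 2 or WT replicate 3 or knockout replicate 2 (adjusted p up to 0.184), Pecam1 without WT replicate 1 or WT replicate 2 or WT replicate 3 (adjusted p up to 0.128).

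Genes with a mean of at least 50 in 1 genotype and at most 1/16 of it in the other were 34 on the knockout side, 15 of them protein-coding, with 1.38% of the knockout values, and 11 on the WT side, 8 of them protein-coding, with 0.177% of the WT values. Among the former, chosen after their values were seen, were Shd, 50.8-fold higher, and Dnah2, a dynein heavy chain of cilia, 69.3-fold higher. Among the latter were S100a11, 27.6-fold lower, and Ndor1, 26.4-fold lower.

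In Camp, Rps29, Igkc, Ssr4 and Rpl27, 30 of 30 values were whole multiples, within 0.01 of a read, of the step of the same-numbered library of the other genotype, against 4 of 150 comparisons with the other steps. Fractional counting of reads shared between genes would give at most about 1 in 50 such values, and 30 of 30 argue against it. Only 1 of the 30 values was whole, within 0.01 of a read, with its own library's step. With the genotypes exchanged, DESeq2 gave the deposited p within 0.0172 in log10 for Camp, against 0.214 as headed. The gaps were 0.00996 against 9.64 for Rps29, 0.00498 against 4.48 for Igkc, 0.00587 against 3.15 for Ssr4 and 0.000519 against 0.0591 for Rpl27. Among other genes the 99th percentile of the gaps was 0.00328 and the largest 0.0817. For these 5 genes the steps argue against the columns as headed, and so do the gaps. That of Rpl27 does so less, as it lay above the 99th percentile but below the largest. An exchange of the genotypes in these rows, with which the log2 fold change of Camp footprints is 1.24 in place of -1.24, stays a candidate. The values do not show at which step it may have arisen. No biological explanation was tested.

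Scatter between libraries, as the squared deviation of pairs of libraries over that of counting, was larger in the knockout, with an index of 5.09 to 5.19 against 1.19 to 1.20 in WT for genes of 10 to 50 reads, all libraries thinned to 1000000 reads. The lowest knockout index of 5.09 at this equal depth argues against depth, and a rise of the index minus 1 by only 1.25 times over a 26.3-fold rise in reads argues against variation that scales with a gene's level. Repeated reading of fewer molecules may contribute and stays open: WT libraries thinned to the matching 241494 reads had 13146 genes with a read, a difference of -15.5% ± 2.43 (SD) from the knockout libraries. That value lies beyond a bound of 15% fixed before by less than its SD. The rule that takes the SD into account was added after the value was seen, and without it the test would have argued against this explanation. The matching depth came from the full-depth knockout reads, divided by the mean index of 5.15 measured at 1000000 reads. At full depth the mean index was 6.04, which gives a lower matching depth that was not run. The test therefore cannot decide this explanation. Genotype stays open, as untested.

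Above 10 normalized reads fold changes rose with abundance, from a median log2 fold change of -0.52 for genes of 10 to 30 to 0.60 above 1000, while genes of 1 to 3 had -0.097 and of 3 to 10 -0.62. Summed values, which need no pseudocount, gave a ratio 1.85 times higher in the top class, a difference of 1.07 between the medians of these classes remained at equal depth, and 1.1 without the 20 most abundant genes, which argues against sparse reads, depth and a few dominant genes as the whole cause. Cyclic loess, which removes this trend, left B cell, ribosomal protein, histone, stem cell and interferon-stimulated genes past the threshold, ended the calls of heat shock and proteostasis, erythroid and translation factor genes, and brought antimicrobial, mitochondrially encoded and Mov10-associated genes past it as lower. Of the lists that lost their calls, the median went from 0.45 to 0.38 for erythroid, from 0.46 to 0.28 for heat shock and from 0.12 to 0.026 for translation factor genes. The median of all genes went from -0.17 to -0.00094. Genes were classed by their mean over both genotypes, so the knockout values, which scattered more, entered both the class and the fold change. The tests of the trend used these same classes and cannot show how far this raises it. A genotype effect may underlie the trend and stays open, as untested.

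The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In limma 1 of 10 splits, the real one, gave as many genes (3628, highest other 0) and 1 of 10 as many lists (8, highest other 0). At an unadjusted p under 0.05, limma gave 5846 genes in the real split and 194 to 271 in the others. Splits other than the real one mix the genotypes, so the difference between genotypes adds to the spread within their groups and lowers their counts. They are therefore no reference for what chance alone would give.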
